A study of Populus trichocarpa with 24 samples.

How the data were processed

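RNA was sequenced from 8 groups of 3 samples of Populus trichocarpa. Per the labels' protocols the trees were 6 months old and grown in a greenhouse, phloem and xylem were scraped from opened stems, and primary roots came from young seedlings rooted in water, although the age given for the roots is 6 months too. Fiber, vessel and mixed cells were cut out by laser microdissection, and only their RNA was amplified before library preparation. Amplification is therefore wholly confounded with the difference between captures and tissues. The labels do not tie captures or tissues to trees, and how cells were recognised is not given in the sources used here.

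The authors deposited 1 table of raw counts per gene, whole numbers that were not normalized. Reads were processed with TopHat, per the submitters' processing notes, with no version given. The counting tool, the genome build, the annotation and the strand setting are not given in the sources used here, so reads of near-identical gene copies may have been divided in ways that cannot be traced. Each of the 24 columns matched 1 sample title, 0 columns were left without a sample, and 0 lines held something other than a gene. The reference table used here (assembly P.trichocarpa_v4.1) matched 0 of the 41335 identifiers. Locations, lengths, GC content and product names were therefore not used here, a check of length or GC bias was void, and 23 lists that select genes by product name, marker lists of other cell types among them, could not be applied.

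Gene groups were followed with 6 lists of 66 identifiers. They were fixed before the data were examined, like the tests, the alternatives and the rule for named genes, from published poplar nomenclature as recalled, with no annotation at hand. The files do not pair identifiers with names, and the check of each listed identifier against a product name could not be made, so a list may hold a wrongly assigned locus. For this reason no gene names are given and loci of a list are described as a group. The rule had called for the 2 most abundant called members of each list, the strongest 10 loci with a product name in each direction, and every member of the secondary wall cellulose synthase, NAC and MYB lists. Its part on product names gave no gene, and the members of the lists are summarised. At most 2 identifiers in each direction are printed for a comparison, taken after the results were seen from the 2 largest changes each way among called loci with at least 50 CPM in the higher group and no overlap of libraries. Another 3 lists, drawn up after the library totals and identifiers had been seen, were analysed and then removed, because nothing in the sources pairs their identifiers with names.

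The deposited counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9. Low-count genes were removed with edgeR's filterByExpr, libraries were scaled by TMM, and groups were compared with the quasi-likelihood test. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and an absolute log2 fold of at least 1. CPM values are edgeR's, with the scaled library sizes, except in the figure of list sums, which uses the unscaled totals, and standard errors were the absolute log2 fold divided by the square root of F. The 15 tissue libraries were fitted together (31308 genes, biological coefficient of variation 27.5%), as were the 9 captures (22828 genes, 111.3%) and the 6 libraries of the mix and xylem tissue (25245 genes, 36.9%). For genes higher in 1 group than in each other, the largest p of the comparisons was taken and adjusted. Lists with at least 3 tested members were tested with limma's camera, two-sided, with the correlation between genes preset at 0.01 and again estimated, adjusted over the lists of a comparison. Enrichment among tissue-high loci used a one-sided Fisher's exact test against all tested loci. Where a group had no count, a fold was bounded with 3 counts over the group, which covers counting error only.

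Replicates differed by more than sampling noise, with chi-square per degree of freedom from 5.5 to 225.2, and none was merged. The replicate numbers in the labels were checked as pairs by correlating deviations from the group means. Of 14 pairs of groups 3 exceeded 0.1 for all numbers: xylem with shoot tip (0.33, 0.19 and 0.36), with leaf (0.13, 0.22 and 0.33) and with phloem (0.14, 0.40 and 0.15). Numbers were taken as pairing those samples only, from the data and not from the labels. Shoot tip, leaf and phloem did not exceed 0.1 for all numbers with each other, so the pairing is uncertain. The main tests used no block, and pairing entered only the alternative with a replicate block.

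The method was tested on simulated data drawn from the real means, pooled over groups, and the library sizes, with 50 changed genes at each fold. So few changed genes make the adjusted threshold stricter than where many loci are called, so recovery there may be understated. A fold of 2 equals the fold threshold, which alone removes many such genes. For xylem against leaf 30, 72, 94 and 98% were recovered at folds of 2, 4, 8 and 16. For fiber against vessel 0, 0, 6 and 18% were recovered, for the mix against xylem 4, 46, 74 and 90%, and for xylem against each other tissue 6, 62, 90 and 100%. Alternatives were DESeq2, other scalings, other count filters, no fold threshold, a replicate block, fits of 2 groups or of all 24 libraries, an estimated correlation, and each library left out. Thinning the captures to the smallest library and limma voom with sample weights were added after the data were seen.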

Results

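Gene expression was measured by RNA sequencing in 24 libraries of black cottonwood (Populus trichocarpa), in 8 groups of 3 libraries each. Groups were 5 tissues (shoot tip, leaf, phloem, primary root and differentiating stem xylem) and 3 laser-captured samples of developing wood: fiber cells, vessel cells, and a mixture of fiber, vessel and ray cells, called the three-cell mix. Fibers are the cells that give wood its strength, vessels conduct water, and ray cells run across the stem. The table held raw counts for 41335 loci, of which 2848 had no count in any library. Library totals ran from 5689642 counts (root replicate 1) to 30917688 (leaf replicate 2) in the tissues, and from 8317935 (fiber replicate 1) to 18040299 (mix replicate 3) in the captures. Fewer loci were detected in the captures, with 20706 ± 1089 (SD, n = 3) in fiber, 19893 ± 2246 in vessel and 27429 ± 1272 in the mix, against 31615 ± 741 in xylem tissue. Vessel libraries also resembled each other less: the median Pearson correlation across genes within the group was 0.70, against 0.84 in fiber, 0.95 in the mix and 0.97 to 0.98 in the tissues, and genes are not independent replicates. Between groups the median was 0.75 for vessel with the mix and 0.72 for vessel with xylem tissue, above that within vessel. For fiber with the mix it was 0.87, above that within fiber. Lower medians were those of fiber with vessel (0.68) and of fiber with xylem tissue (0.8). The replicates are not stated to come from separate trees, so p-values measure only the spread between these samples.

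**Figure D1:**
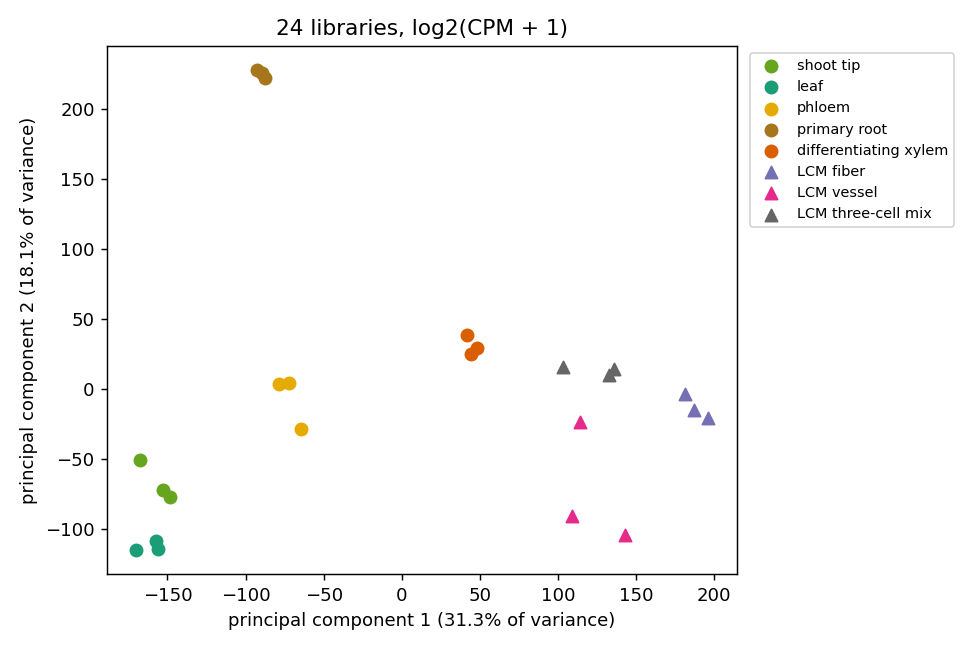
Principal components of log2(CPM + 1) in the 24 libraries, 1 point per library, with component 1 (31.3% of the variance) on the horizontal and component 2 (18.1%) on the vertical axis. Circles are tissues and triangles are laser captures, with 3 libraries of each group in 1 colour.

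Groups of genes were followed through 6 lists of locus identifiers, 66 loci in all, drawn up before the data were examined for lignin precursor (monolignol) synthesis, secondary wall cellulose synthases, primary wall cellulose synthases, xylan synthesis, and the NAC and MYB transcription factors that control wood formation. Neither the deposited table nor the reference used here pairs these identifiers with gene names, so membership of the lists rests on published poplar nomenclature as recalled when the lists were fixed and was not checked here. Single loci are given by identifier alone.

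Expression in differentiating xylem was compared with each of the other 4 tissues to find the genes that stand out in forming wood. In xylem the 5 secondary wall cellulose synthase loci together reached 9038 ± 1650 CPM (SD, n = 3), against 268.6 ± 38.9 CPM in phloem, the highest of the other tissues, and all 5 were higher in xylem than in every other tissue. The smallest of the 4 log2 folds lay between 4.40 and 5.25 for these loci. All 11 xylan loci were likewise higher in xylem than in each other tissue, with smallest log2 folds of 3.34 to 6.44, and summed to 5311 ± 497 CPM against at most 194.1 ± 13.4. Of the 22 monolignol loci, 20 were higher in xylem than in each other tissue, by log2 folds of at least 1.36, and the list summed to 32570 ± 2155 CPM against 7224 ± 641.9 in leaf and 6135 ± 50.5 in root, whose order is the opposite on unscaled library totals. The wood regulators were far less abundant but followed the same direction, with 9 of 12 NAC loci and 4 of 4 MYB loci called, the NAC list summing to 469.1 ± 44.6 CPM and the MYB list to 84.2 ± 17.4 CPM in xylem. By edgeR's quasi-likelihood test none of the 12 primary wall cellulose synthase loci was called higher in xylem than in each other tissue. Their sum of 1344 ± 150.6 CPM in xylem lay within the 959.9 to 1678 CPM of the other tissues. In all 1616 of 31308 loci were higher in xylem than in each other tissue, called on the largest p of the 4 comparisons, Benjamini-Hochberg adjusted over loci. Among them the lists were over-represented by Fisher's exact test, one-sided, with adjusted p = 2e-23 for monolignol synthesis, 2e-14 for xylan, 9.8e-10 for the NAC loci, 5.4e-07 for the secondary wall cellulose synthases and 8.5e-06 for the MYB loci. This test treats loci as independent, while members of a list move together, so these values overstate the evidence. In the camera tests below, only the monolignol list passed against every other tissue with an estimated correlation between genes.

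**Figure D2:**
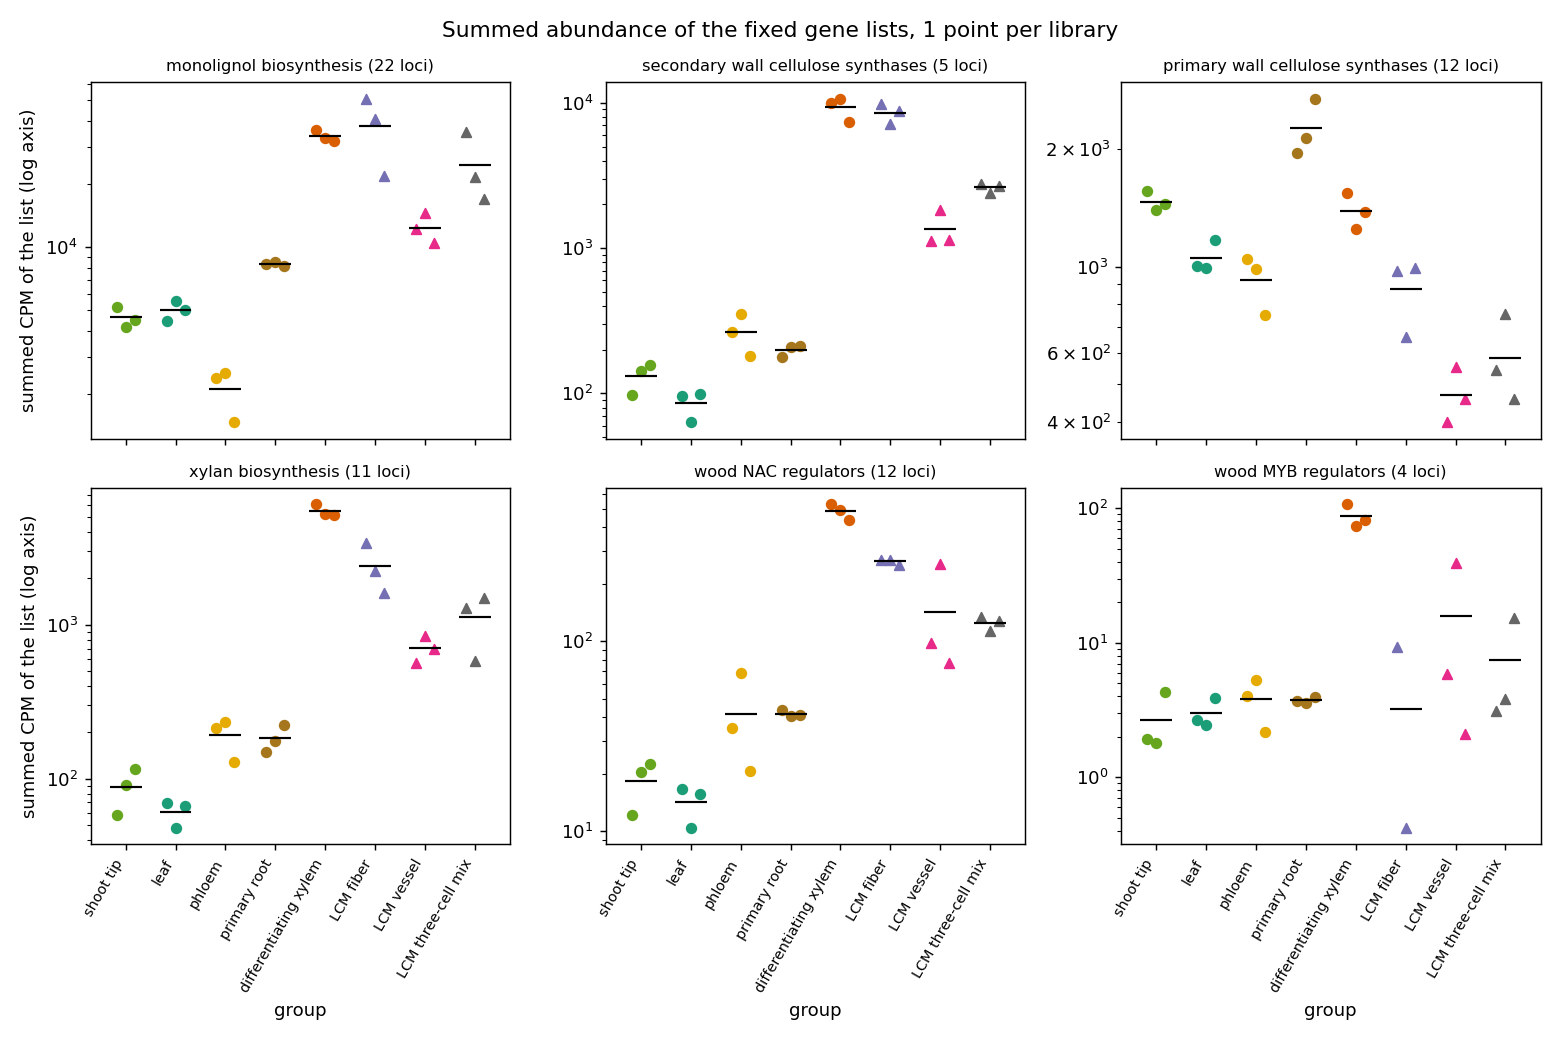
Summed CPM relative to library totals (log axis) for each of the 6 gene lists in the 24 libraries, 1 point per library, with a bar at the mean of each group of 3. The secondary wall cellulose synthases and the xylan loci lie highest in differentiating xylem and in the fiber captures, and 1 fiber library with no count for the MYB loci is not drawn. In phloem replicate 3, 31 loci outside the lists took 37.726% of the total, which lowers its points by construction.

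Against phloem, the tissue on the other side of the cambium, all 22 monolignol loci were higher in xylem, with a median log2 fold of 4.23 and standard errors of 0.19 to 0.41. The 5 secondary wall cellulose synthases (median 5.10), the 11 xylan loci (median 5.04), 11 of 12 NAC loci (median 3.38, or 3.26 with 1 locus absent from phloem taken at its lower bound) and 4 MYB loci (median 4.62) were higher as well. Among the primary wall cellulose synthases 2 of 12 were higher, with a median of 0.47. Of the NAC calls 1 rested on 13 counts in xylem and 0 in phloem, and was lost without xylem replicate 2 or 3 or phloem replicate 1 or 2. The same numbers of loci were called when adjusted over the list alone. By limma's camera test the adjusted p-values were 1.2e-20 for monolignol synthesis, 3.7e-07 for the secondary wall cellulose synthases, 3.1e-12 for xylan, 3.3e-07 for NAC and 6.2e-04 for MYB loci, and with an estimated correlation between genes they were 0.0012 for monolignol synthesis and 0.046 for each of the others. The edgeR test called 11267 of 31308 loci, 5426 higher and 5841 lower in xylem. Potri.019G121100 had 101.4 ± 89.8 CPM in xylem (SD, n = 3) and 3 counts in the phloem libraries together, while Potri.017G051200 had 62.0 ± 30.6 CPM in phloem and 1 count in the xylem libraries together.

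Against shoot tip, 21 of 22 monolignol loci were higher in xylem and the remaining locus was at a log2 fold of -0.47 that was not called. The median log2 fold was 3.92 for monolignol synthesis, 6.14 for the 5 secondary wall cellulose synthases, 5.93 for the 11 xylan loci and 5.0 for the 4 MYB loci, all members of the last 3 lists being higher. Of the NAC loci, 10 of 12 were higher, with a median of 3.49. Primary wall cellulose synthases went the other way where they were called, with 3 of 12 lower in xylem, and for this list the median (0.17) and the mean (-0.22) differed in sign, with a camera adjusted p of 0.91. Counts adjusted over the list alone were identical. The camera adjusted p was 4.5e-14 for monolignol synthesis and remained at 0.0051 with an estimated correlation. For the secondary wall cellulose synthases (2e-06), xylan (7.3e-11), NAC (1.1e-05) and MYB loci (0.0014) the preset-correlation call was lost, at adjusted p = 0.067, 0.067, 0.083 and 0.074 with an estimated correlation. In this comparison 14343 loci were called by edgeR, 6050 higher and 8293 lower in xylem. Potri.007G139200 had 58.8 ± 15.7 CPM in xylem (SD, n = 3) and 3 counts over the shoot tip libraries, and Potri.019G005600 had 104.7 ± 58.6 CPM in shoot tip and 0 counts in xylem.

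Against leaf, 20 monolignol loci were higher in xylem and 1 was lower, with a log2 fold of -1.70. Primary wall cellulose synthases went both ways, 2 of 12 being higher and 3 lower in xylem, with a median of -0.14. All secondary wall cellulose synthase, xylan and MYB loci were higher, with median log2 folds of 6.31, 6.10 and 4.04. The NAC list had 10 of 12 loci higher, at a median of 2.97, and 1 lower when adjusted over the list alone, where the other counts were identical. Of these 10, 1 locus with a log2 fold of 1.22 and an edgeR adjusted p of 0.046 was not called with the replicate block, nor without xylem replicate 1 or 2 or leaf replicate 2 or 3. The camera adjusted p-values were 3.5e-12 for monolignol synthesis, 7.4e-06 for secondary wall cellulose synthases, 9.8e-10 for xylan, 8.7e-05 for NAC and 0.0036 for MYB loci. With an estimated correlation they were adjusted p = 0.0086 for monolignol synthesis and 0.084, 0.084, 0.12 and 0.10 for the others. The edgeR test called 15517 loci, 6426 higher and 9091 lower in xylem. Potri.003G132000 had 215.9 ± 11.8 CPM in xylem (SD, n = 3) against 0.343 ± 0.112 in leaf, and Potri.003G066700 had 175.4 ± 66.2 CPM in leaf and 0 counts in xylem.

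Against primary root, which came from water-rooted seedlings and not from the trees, the monolignol list differed least, with 21 of 22 loci higher in xylem at a median log2 fold of 2.32. The 5 secondary wall cellulose synthases (median 5.88), 11 xylan loci (5.57) and 4 MYB loci (5.15) were all higher in xylem. Of the NAC loci 10 were higher and 1 was lower, with a log2 fold of -2.98. Primary wall cellulose synthases were lower in 4 and higher in 2 of 12 loci. Adjusted over the list alone the counts were identical. The camera adjusted p-values were 3.3e-11 for monolignol synthesis, 4.8e-06 for secondary wall cellulose synthases, 1.1e-09 for xylan, 1.4e-04 for NAC and 9.7e-04 for MYB loci, and adjusted p = 0.012, 0.067, 0.067, 0.13 and 0.067 with an estimated correlation. In total 15219 loci were called by edgeR, 6640 higher and 8579 lower in xylem. Potri.012G015000 had 1110 ± 874.8 CPM in xylem (SD, n = 3) against 0.321 ± 0.327 in root, and Potri.006G057900 had 959.5 ± 284.9 CPM in root and 0 counts in xylem.

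The other tissues were treated in the same way, so that each received the loci higher in it than in each of the other 4. Root had 3197 such loci, leaf 2779, phloem 817 and shoot tip 297, by the edgeR test. No locus of the monolignol, secondary wall cellulose synthase, xylan, NAC or MYB lists was among those of any tissue but xylem. Among the primary wall cellulose synthases 2 loci were highest in root, with smallest log2 folds of 1.40 and 1.71, and 1 was highest in shoot tip, at 1.26. Fisher's exact test gave the primary wall list an adjusted p of 1.0 in root and 0.66 in shoot tip. The shoot tip count fell to 192 without leaf replicate 1 and to 147 without leaf replicate 2.

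Fiber and vessel captures were compared to separate the main cell types of wood. Secondary wall cellulose synthases summed to 9118 ± 1796 CPM in fiber and 1351 ± 369.8 CPM in vessel captures (SD, n = 3), and 4 of 5 loci were called higher in fiber, with log2 folds from 2.20 to 3.33. Monolignol loci summed to 40640 ± 17430 CPM in fiber and 12330 ± 1919 CPM in vessel. All 22 had a positive fold, 15 were called higher in fiber, and the median log2 fold was 1.96. Of the 11 xylan loci 3 were called higher in fiber (sums of 2598 ± 1099 and 699.3 ± 128.7 CPM), with a list median of 1.81. Adjusted over the list alone, 18 monolignol, 5 secondary wall cellulose synthase, 7 xylan and 2 of 12 primary wall cellulose synthase loci were higher in fiber, none of the last being called over all genes. The camera adjusted p was 1.7e-05 for the secondary wall cellulose synthases and 0.04 with an estimated correlation. Those of monolignol synthesis (1e-10) and xylan (0.0056) were lost, at adjusted p = 0.23 and 0.28 with an estimated correlation, and the primary wall list was at 0.10.

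Of the wood regulators, 9 of 12 NAC and 2 of 4 MYB loci could be tested in the captures. The NAC list summed to 279.8 ± 20.4 CPM in fiber and 139.1 ± 94.8 CPM in vessel (SD, n = 3). Its most abundant 2 loci, at 127.2 ± 12.01 and 116.3 ± 25.2 CPM in fiber, had every fiber library above every vessel library, with log2 folds of 1.87 ± 0.64 and 1.91 ± 0.61 (SE) and edgeR adjusted p-values of 0.11 and 0.093. Both were called without vessel replicate 2, at log2 folds of 2.77 and 2.42, and the latter was also called by DESeq2. No NAC locus was called by edgeR in the fit of the 9 captures, while a fit of all 24 libraries called 3 of them, 2 higher and 1 lower in fiber. The folds lay on both sides of 0 with a median of -0.74 and a camera adjusted p of 0.66, and none was called when adjusted over the list alone. Neither MYB locus was called by edgeR in the fit of the 9 captures, while DESeq2 and the fit of all 24 libraries called both, and 1 was higher and 1 lower in fiber when adjusted over the list alone. The higher one had counts in fiber replicate 1 alone among the fiber libraries and 0 counts in vessel. Its fold bound of 32.2, by 3 counts over the vessel group, therefore rests on 1 library, without which the log2 fold was 0. The other MYB locus had a log2 fold of -7.34 ± 2.40. The MYB median therefore rests on few counts, being 0.50 as fitted and -1.17 with the first locus at its bound.

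Loci highest in xylem tissue lay higher in fiber, and those highest in phloem and in shoot tip lay lower. The tests on these sets were chosen after the results were seen. Those highest in shoot tip had a median log2 fold of -0.76, those highest in leaf -0.46 and those highest in root -0.03, with camera adjusted p-values of 0.016, 0.39 and 0.97 with an estimated correlation. Only 90 of the 297 loci highest in shoot tip could be tested in the captures. Of the loci highest in xylem tissue, 1503 were tested, 265 were called higher in fiber and 26 lower, and their median log2 fold was 1.29, with a camera adjusted p of 0.0067 with an estimated correlation. Of the loci highest in phloem, 457 were tested, 2 were higher and 33 lower in fiber, with a median of -1.60 and an adjusted p of 0.016 with an estimated correlation. Over all genes 1380 of 22828 loci were called by edgeR, 652 higher and 728 lower in fiber. The count was 599, 733 and 753 without fiber replicates 1, 2 and 3. Simulated changes of 16-fold were recovered for 18% of loci, but few genes were changed there, which makes the adjusted threshold stricter. In the real data monolignol loci were called from a log2 fold of 1.37. Potri.019G093400 had 146 ± 44.4 CPM in fiber (SD, n = 3) and 2 counts in vessel, and Potri.010G195800 had 57.5 ± 15.8 CPM in vessel and 0 counts in fiber.

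**Figure D3:**
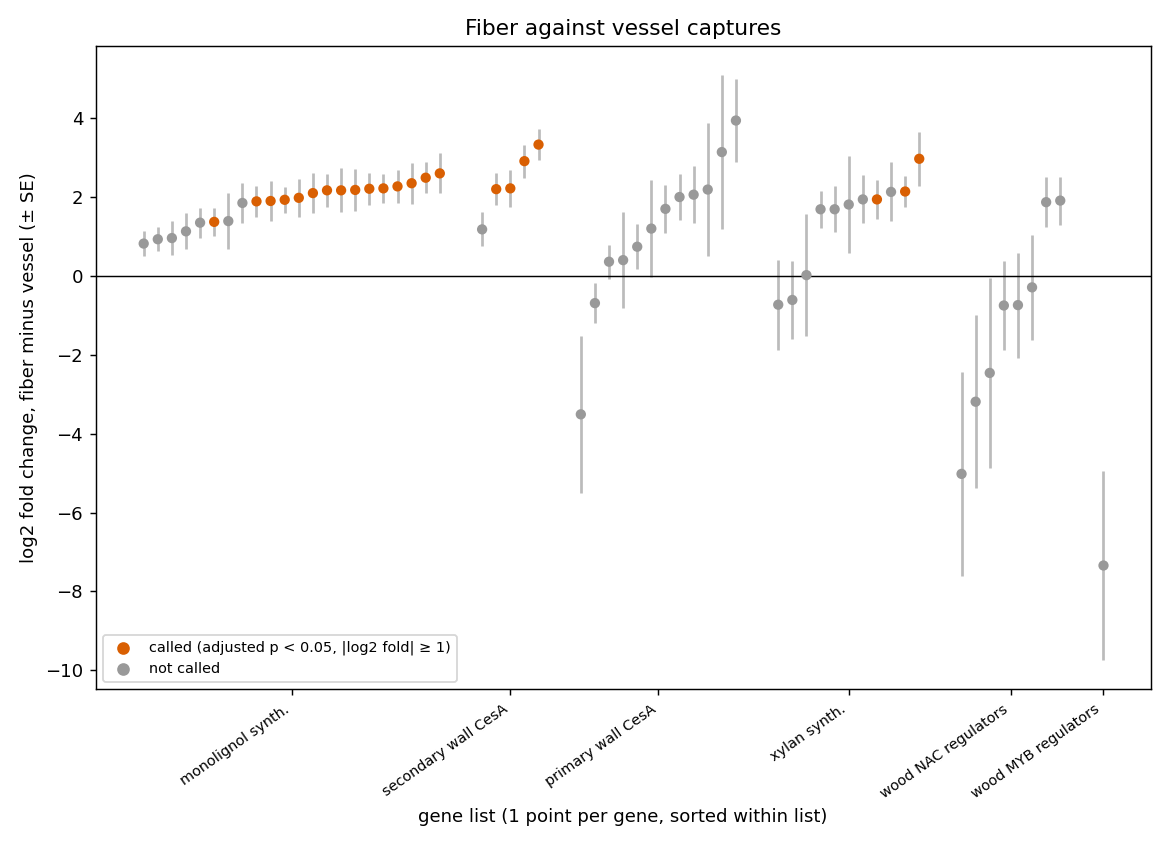
Log2 fold change, fiber minus vessel, of each tested locus of the 6 lists, sorted within its list, with bars of 1 standard error from the edgeR fit. Orange points were called and grey points were not, all 22 monolignol loci lie above 0, and 2 loci with no count in vessel are not drawn.

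Against the three-cell mix, fiber captures held more secondary wall cellulose synthase transcript, with sums of 9118 ± 1796 and 2515 ± 209.2 CPM (SD, n = 3). Of the 5 loci 1 was called higher in fiber over all genes, at a log2 fold of 2.12 and an edgeR adjusted p of 0.043, and 5 were higher when adjusted over the list alone. The list had a median of 1.51 and a camera adjusted p of 8.9e-12, or 0.0054 with an estimated correlation. All 22 monolignol and all 11 xylan folds were positive, with medians of 0.86 and 0.96, but no locus was called by edgeR in the fit of the 9 captures, and 0 and 1 passed when adjusted over the list alone. Their camera adjusted p-values of 3.5e-17 and 3.8e-07, and that of 0.0052 for primary wall cellulose synthases (median 0.58), were each at adjusted p = 0.07 with an estimated correlation. Neither the NAC loci, with a median of -0.69 against an upward camera test at adjusted p = 0.38, nor the 2 MYB loci held a member called by edgeR in that fit. By DESeq2 3 more secondary wall cellulose synthase loci were higher and 1 MYB locus was lower in fiber. By limma voom with sample weights NAC loci were called higher at log2 folds of 1.92 and 1.55, the former also in the fit of all 24 libraries (1.89). Both of these settings called more secondary wall cellulose synthase loci too, and the fit of all 24 libraries called the same MYB locus lower. By edgeR 79 loci were called, 15 higher and 64 lower in fiber. The call of the secondary wall cellulose synthase locus was lost without any 1 of the 6 libraries, and the total was 21, 32 and 21 without fiber replicates 1, 2 and 3 and 16, 36 and 31 without mix replicates 1, 2 and 3.

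Between vessel captures and the three-cell mix edgeR called no listed locus in the fit of the 9 captures, while DESeq2 called 1 and a fit of all 24 libraries 3 of the 16 secondary wall cellulose synthase, NAC and MYB loci. The monolignol list had a median log2 fold of -1.10, with 21 of 22 folds negative and 9 loci lower in vessel when adjusted over the list alone. Its camera adjusted p of 0.036 became adjusted p = 0.95 with an estimated correlation. The secondary wall cellulose synthases had a median of -0.72, with 1 locus lower when adjusted over the list alone, and the primary wall list and the xylan list had medians of -0.61 and -0.68, none called. For xylan the camera test pointed upward at an adjusted p of 0.94, and for the NAC list the median was 0.45 and the mean -0.08. Only 3 of 22828 loci were called by edgeR, all lower in vessel, with 2918 at an unadjusted p below 0.05 and 1887 called by DESeq2. Potri.019G093400 was among them, with 50.8 ± 38.9 CPM in the mix (SD, n = 3) and 2 counts in vessel. The count was 264 without vessel replicate 1, 11 without vessel replicate 3, and 0 without vessel replicate 2 or mix replicate 1 or 2, and upper-quartile and median-of-ratios scaling moved the median of all genes by -0.16 and 0.15.

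Ray cells were captured only within the mix, so loci above both pure captures were sought. By the edgeR test 0 loci were higher in the mix than in both fiber and vessel, with 197 at an unadjusted p below 0.05 and 7 called by DESeq2. Among simulated genes raised 16-fold in the mix 22% were recovered. No locus of the 6 lists was called, and the smallest folds of the lists had medians from -0.86 for monolignol synthesis to -1.51 for the secondary wall cellulose synthases.

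The three-cell mix was compared with xylem tissue, from which it differs in cell content and in having been captured and amplified, so that these cannot be separated. Loci of 5 lists were mostly lower in the mix. Xylan loci fell from 5622 ± 609.3 CPM in tissue to 1100 ± 448.6 in the mix (SD, n = 3), all 11 being called, with a median log2 fold of -2.92. Secondary wall cellulose synthases were lower in 5 of 5 loci (median -2.10), NAC loci in 8 of 10 (median -2.40), MYB loci in 4 of 4 (median -4.06) and primary wall cellulose synthases in 8 of 12 (median -1.44). Monolignol loci were mixed, 10 being lower, 1 higher at a log2 fold of 1.84 and 11 not called, and their sums of 24590 ± 10270 and 34470 ± 2743 CPM overlapped. Adjusted over the list alone 9 primary wall cellulose synthases were lower and the other counts were identical. By camera the adjusted p-values were 5.9e-05 for xylan, 3.3e-04 for primary wall cellulose synthases, 6.9e-04 for NAC, 0.0018 for secondary wall cellulose synthases, 0.0018 for monolignol and 0.01 for MYB loci, all lost at adjusted p = 0.41 for monolignol synthesis and 0.18 for the other lists with an estimated correlation. Every mix library lay below every tissue library for 29 of the 30 tested loci of the xylan, secondary wall cellulose synthase, NAC and MYB lists, for 10 of 12 primary wall cellulose synthases and for 14 of 22 monolignol loci, with 1 monolignol locus wholly above. A locus without change does so by chance in 5% of cases in this direction, but members of a list move together and many loci outside the lists were lower too. The edgeR test called 9645 of 25245 loci, 4270 higher and 5375 lower in the mix. Potri.004G140800 had 171.1 ± 66.1 CPM in the mix and 0.164 ± 0.144 in tissue, and Potri.013G152500 had 87.3 ± 17.8 CPM in tissue and 0.105 ± 0.181 in the mix.

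**Figure D4:**
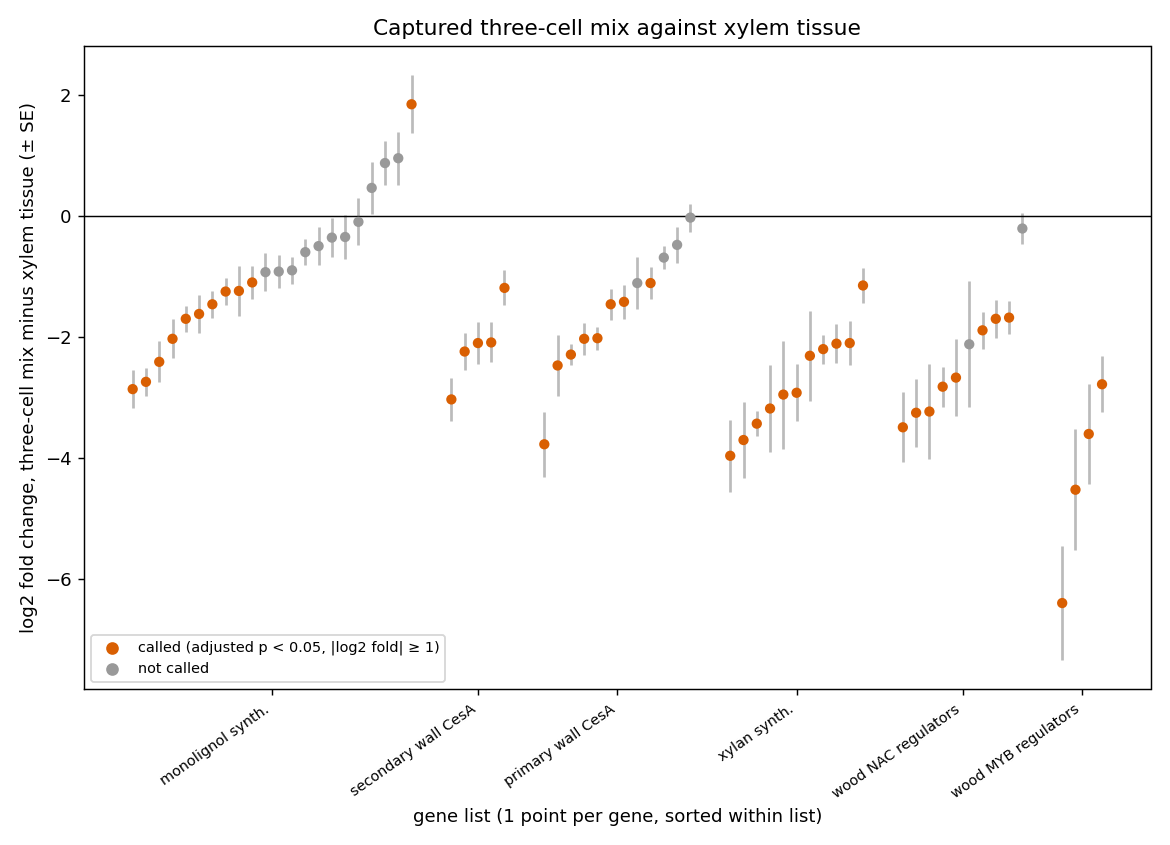
Log2 fold change, three-cell mix minus xylem tissue, of each tested locus of the 6 lists, sorted within its list, with bars of 1 standard error from the edgeR fit. Orange points were called and grey points were not, and all xylan, NAC and MYB points lie below 0.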

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

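Thinning and limma voom with sample weights were chosen after the data were seen, and all other alternatives before. The settings were followed for the loci of the naming rule only, not for every listed locus. Of these, the loci called in a comparison, 134 cases in all, kept their direction in 1988 of 1988 values, and 1907 stayed called while 81 did not. The setting without a fold threshold is among these values, and by construction it could neither end a call nor change a direction. The largest share was lost between fiber and the mix, 7 of 17 values of 1 locus, followed by fiber and vessel, 23 of 136 values in 6 of 8 loci. Across scalings the share of higher calls moved by at most 6.4 percentage points, and the median of all genes moved by over 0.1 in xylem against leaf (0.17, upper quartile) and vessel against the mix (-0.16 and 0.15).

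The counts of xylem against each other tissue stayed within 1.5 times the reported values in all settings but 1. With all 24 libraries in 1 fit, which pools their spread with that of the captures, they fell to 6964 for xylem against shoot tip, 8883 leaf, 4393 phloem and 8343 root. Loci higher than in each other tissue then numbered 628 for xylem, 2 for shoot tip, 597 for leaf, 35 for phloem and 1083 for root. That fit called 9369 loci for fiber against vessel, 4067 for fiber against the mix, 6128 for vessel against the mix, 697 above both captures and 5865 for the mix against xylem. DESeq2 called 4776, 1185 and 1887 in the 3 capture comparisons and 7 above both. Only 2 groups in the fit gave 542, 216 and 0, and limma voom with sample weights 353 for fiber against vessel and 1501 for fiber against the mix. Without a low-count filter fiber against the mix gave 133 and vessel against the mix 56. Vessel against the mix also gave 11 with upper-quartile scaling and 0 after thinning. The cause was not tested, except that fewer or more libraries enter the spread by construction.

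With the replicate block vessel against the mix had 0 called loci. Pairing changed no other count by over 1.5 times (fiber against vessel 928, fiber against the mix 57, the mix against xylem 9054), and among the followed loci of the paired tissues it ended 1 call, that of the NAC locus described for xylem against leaf. Lists past the threshold with an estimated correlation numbered 1 for shoot tip, 1 for leaf, 1 for root, 1 for fiber against vessel, 1 for fiber against the mix, 0 for vessel against the mix and 0 for the mix against xylem, from 5, 5, 5, 3, 4, 1 and 6. A correlation above the preset 0.01 raises the variance by construction, but this is not the whole difference. For the primary wall list in fiber against vessel the estimate was 0.01, yet the unadjusted camera p rose from 0.081 to 0.14. Lost calls therefore do not by themselves show that members of a list move together.

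Leaving out 1 library gave 13615 to 14543 loci for shoot tip, 15251 to 15736 leaf, 10309 to 11464 phloem, 14950 to 15429 root, 599 to 2040 fiber against vessel, 16 to 36 fiber against the mix, 0 to 264 vessel against the mix and 7608 to 10617 the mix against xylem. Tissue-high loci ranged from 1419 to 1856 in xylem, 147 to 294 in shoot tip, 2504 to 2863 in leaf, 595 to 848 in phloem and 2739 to 3345 in root, and those above both captures stayed at 0.

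Uncalled followed loci became called in 18 values for fiber against the mix, 11 for fiber against vessel, 4 for vessel against the mix and 1 each for xylem against leaf, xylem against phloem and the mix against xylem, mostly by DESeq2, by voom with sample weights or with all 24 libraries in 1 fit. Of 812 values of uncalled followed loci 36 changed sign or fell to 0, in 11 NAC and MYB loci, with no adjusted p below 0.36. The cause was not tested. Their log2 folds with the replicate block were -3.05, -0.878, -2.13, -0.227 and -0.0492. With voom weights they were -1.86, 1.24, -0.703, -2.40, -0.531 and -0.878, with upper-quartile scaling -0.152 and after thinning -0.00281. Without vessel replicate 2 they were 0.794, 3.82, -1.10, -5.02, -0.869, -0.209 and -0.427, without vessel replicate 1 0.121, without fiber replicate 1 -7.56, 0 and 0, without fiber replicate 3 0.267 and 0.294, and without mix replicate 2 or 3 -0.179, 0.0231 and 0.0972. In the tissues they were -0.214, -0.441 and -0.252 without a xylem library, -0.387 and -0.0754 without a phloem library and -0.194 and -0.0329 without a shoot tip library. Over all leave-outs these loci ranged from -0.441 to 0.758 (xylem against shoot tip), from -0.387 to 4.82 (xylem against phloem), from -7.56 to 1.40 and -1.22 to 0.267 (fiber against the mix), and between fiber and vessel from -1.69 to 0.794, -0.807 to 0.294, 0 to 6.05, -3.84 to 3.82 and 0 to 8.95. Between vessel and the mix they ranged from -0.877 to 0.121, -1.10 to 1.05, -0.427 to 1.95, -0.869 to 0.527, -5.02 to 2.03 and -0.209 to 3.70. In the captures 16-fold changes were recovered in 18% of simulated fiber and vessel genes, in a simulation with few changed genes.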

Other observations

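The tests on the tissue-high loci in the captures and on the matched lists were chosen after the results were seen, and those on the abundant phloem loci and the splits of the samples before. Loci highest in xylem tissue were also higher in fiber than in the three-cell mix, with a median log2 fold of 0.81 over 1503 tested loci, 12 called higher and 3 lower, and a limma camera adjusted p of 8.2e-04 with an estimated correlation. Loci highest in leaf and in phloem lay lower in fiber than in the mix, with medians of -0.76 and -1.0 and adjusted p = 0.061 and 0.066 with an estimated correlation. Those highest in root and in shoot tip had medians of -0.59 and -0.39, at camera adjusted p = 0.31 and 0.38 with an estimated correlation. Vessel captures stood above the mix for loci highest in shoot tip, with a median of 1.06 over 90 tested loci and an adjusted p of 0.023 with an estimated correlation, though none was called singly by edgeR. These 90 are a part of the 297 loci of that set. The set itself was unstable, with 147 loci without leaf replicate 2 and 2 with all 24 libraries in 1 fit. Those highest in phloem had a median of 0.61, at adjusted p = 0.11 with an estimated correlation. Between fiber and vessel, loci highest in shoot tip had a median of -0.76 (adjusted p 0.016 with an estimated correlation), those highest in leaf -0.46 (0.39) and those highest in root -0.03 (0.97).

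Loci highest in phloem lay above the fiber captures in the vessel captures, with a median log2 fold, fiber minus vessel, of -1.60 (bootstrap interval over genes -1.92 to -1.27). Sequencing depth is an unlikely source, since the median was -1.50 after thinning every capture to the smallest library, and no vessel library decided it, since the median nearest 0 without 1 of them was -1.61. A lower share of xylem RNA in the vessel captures was not excluded. It would raise loci of other tissues alike and lower xylem loci, those of the wall lists among them. Against it, loci highest in root had a median of -0.03 (-0.18 to 0.06 over genes) and lay above those highest in phloem in 9 of 9 pairs of a fiber and a vessel library, but the ranges over these pairs overlapped (-0.47 to 0.72, against -1.76 to -0.17). Loci highest in shoot tip went the way of phloem, with a median of -0.76. Those highest in leaf leaned that way (-0.46), but were not called by camera with an estimated correlation. Phloem cells or cells of the cambial zone cut out with the vessels, and expression of these loci in the vessels themselves, also remain open and were not tested.

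The lower level of wood-forming lists in the three-cell mix than in xylem tissue may come from loss of transcripts of their abundance during capture and amplification. Against 10000 random lists matched on abundance in xylem tissue, the median fold of the NAC loci lay at percentile 0.01, of the MYB loci at 0.24, of the xylan loci at 0.13, of the primary wall cellulose synthases at 1.5, of the secondary wall cellulose synthases at 17.77 and of the monolignol loci at 92.8. Random lists ignore that members move together, with estimated correlations of 0.36 (NAC) and 0.57 (xylan), at which camera called none of these lists. The 9 pairs of a mix and a tissue library were compared as well. All lay below the 5th percentile of matched lists for the NAC loci (medians of -3.97 to -1.85 over the pairs, against -0.91) and the MYB loci (-5.75 to -3.07, against -1.76). Not all did for the xylan loci (up to -1.88, against -1.95) and the primary wall cellulose synthases (up to -0.90, against -1.17). The NAC and MYB loci thus lay lower than most loci of like abundance. That percentile ignores common movement too, however, and the pairs share libraries, so abundance alone is not excluded for any list. The MYB loci were also near the floor in the mix, with means of 0.03 to 4.60 CPM. Other effects of amplification and the cell content are confounded with the groups and remain open.

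Phloem replicate 3 held 31 loci at 1000 CPM or more and at least 10 times the mean of the other phloem libraries. They took 37.726% of its counts, against 0.73 and 0.835% in phloem replicates 1 and 2 and 4.416% in root replicate 1, and they include several runs of neighbouring identifiers, the largest with 11 loci. Without them 11253 loci were called between xylem and phloem, and 97.6% of the 11267 called with them were shared, so they did not distort that count. Where these counts come from was not tested.

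Other splits of the samples were counted for each comparison. Each of the 8 comparisons of 3 with 3 libraries has 10 splits, too few for a share under 0.05, and 1 split, the real one, gave as many loci, the highest other count being 0 beside real counts of 14343, 15517, 11267, 15219, 1380, 79, 3 and 9645. For loci higher than in each other tissue 100 splits were drawn. Only 1 of 100, the real one, gave as many for xylem (1616 against a highest other of 0), leaf (2779 against 302), phloem (817 against 633) and root (3197 against 618). For shoot tip 3 of 100 gave as many as the real 297, and the highest other had 791. This may come from a structure of the samples, which was not examined. Each of these shares lay under 0.05. Shuffled labels join different tissues in 1 group, however, which raises the spread within groups and can lower the counts. The shares therefore show that the real labels separate the libraries better than most shuffles, but they do not exclude chance for the loci of a tissue. For the mix above both captures all 100 gave at least the real count of 0, as they must, and the highest other was 0, so these splits decide nothing.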
